A study of Mus musculus with 8 samples.

How the data were processed

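Liver RNA of 8 female Ames mice was measured on Affymetrix mouse U74Av2 arrays, short-oligonucleotide arrays on which each transcript is read by a set of probes near its 3′ end. Per the labels, all 8 animals were phenotypically normal carriers or non-carriers of the recessive Ames dwarf allele, which the labels do not separate, were fed 30% less than the intake of freely fed normal females, and were killed at 24 to 26 months of age. Each label names a mouse of its own, so each array was taken as 1 animal, and the spread between arrays holds both animal and technical differences. The labels give 1 group, so the values below describe the level of each transcript and its spread between animals, and no contrast between groups was made; freely fed and dwarf mice were not analysed here.

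The deposited values are intensities, 1 per probe set and array, on a linear scale. Per the labels, arrays were scanned on a Hewlett-Packard GeneArray scanner, and the image analysis followed an earlier publication; the software, its version and its scaling target are not given in the sources used here. The deposited intensities themselves show the scaling: the mean after trimming 2% of the values at each end lay between 500.38 and 500.41 on each array, while the medians ran from 132 on replicate 5 to 166 on replicate 4, a difference of 26.1%. Background and mismatch handling before deposit are likewise not given in the sources used here. The table held 12488 probe sets, of which 66 were Affymetrix controls.

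Because the medians differed by over 10%, the rule fixed beforehand called for quantile normalization, which was run over the 12422 other probe sets. Quantile normalization gives each array the same set of values, so the brightest transcripts can differ little between arrays by construction. Values under the 20th percentile of the positive values (a signal of 24.6) were raised to it before log2 was taken. The 6211 probe sets with a mean log2 signal above the median of all were kept, and they named 4810 genes. Gene symbols came from the platform annotation, set against the NCBI RefSeq gene table of assembly GRCm38.p6 through gene identifiers; 10833 probe sets had 1 symbol, 396 had several and were left unnamed, and 1193 had none. No symbol changed in that step. No coordinates are given, since the arrays carry no genome build. Where several kept probe sets named a gene, the brightest was used.

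The test for variable probe sets used limma (3.58.1, in R 4.3.3): the variance of the log2 values over 8 arrays (7 residual degrees of freedom) was divided by a prior variance that follows the mean level and is robust to outlying probe sets (4.03 prior degrees of freedom), with a 1-sided F test and Benjamini-Hochberg adjustment at 0.05. A variance ratio above 0 on the log2 scale thus means more spread than transcripts of like level. The 36 lists of pathway genes and cell type markers, 651 genes of which 513 were on the array under 1 symbol and 383 were kept, were fixed before the data were examined, and so were the tests and the rule for named genes. A list with at least 5 kept genes (29 lists) was tested for variability, its median log2 variance ratio against 10000 random lists of the same size and level (2-sided), and for coherence, its mean pairwise correlation across arrays against 10000 random lists matched on level and variance ratio (1-sided). Both families were adjusted over the 29 lists; the smallest 2-sided p that the random lists can give is 0.0002. A list score is the mean of the members' log2 values after each gene's own mean is subtracted. For 14 pairs of lists fixed beforehand, scores were correlated with an exact 2-sided permutation test over the 40320 pairings of the 8 arrays. The share of the first principal component was set against 1000 data sets in which each probe set was shuffled over arrays.

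The rule for named genes took the 15 most variable genes past the threshold (none passed), the 3 members with the highest variance ratio of each list that passed a test and, for coherence, the 3 with the highest mean correlation with the other members, the 2 brightest and 2 most variable members of each other list, and 12 genes of the diet and growth hormone axes named in advance. It gave 137 measured genes. G6pc1 is listed in the tables used here as G6pc. Saa1 had no probe set with that symbol alone and was not analysed here, and 1 item is not reported here. 3′ over 5′ ratios came from the control probe sets for Gapdh, pyruvate carboxylase and β-actin, on the deposited scale. The mean signal of the bacterial and phage spike-in control sets was taken on the same scale. Since each array was scaled to a like trimmed mean, this signal does not by itself measure the labelling of the liver RNA.

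The alternatives were the deposited scaling, a floor at the 40th percentile, no filter or a filter at the 75th percentile, each array left out, the first principal component removed, the mean over the probe sets of a gene, shared-sequence probe sets left out, other priors, an offset in place of the floor and other list scores; 3 more were added after the data were examined. The tests were checked on simulated data before use. With 50 of 6211 probe sets given a standard deviation 2, 4, 8 or 16 times that of their level and the prior as estimated, the variance test found 0%, 8%, 36% and 90% of them; with 20 prior degrees of freedom it found 34%, 92%, 100% and 100%. A planted coherent list and a planted variable list each passed at an adjusted p of 0.0029, and 0 others of the 29 lists did. These lists were made of simulated values. The count of 0 is therefore not the rate of false list calls on the measured arrays, where replicates 5 and 6 lay apart. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The number of arrays, 8, limits the precision of every value.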

Results

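The data set held 8 liver arrays from 8 calorie-restricted female Ames mice, a single group with n = 8. The Ames stock carries a recessive pituitary dwarfism allele, and the animals here were phenotypically normal, killed at 24 to 26 months after feeding at 30% below the intake of freely fed mice. The label keywords place them in work on caloric restriction and the Ames dwarf. With 1 group, the question open to these arrays is how far each hepatic transcript differed from animal to animal. Levels are quantile-normalized signals in arbitrary units, given as mean ± SD over the 8 arrays, each of which the labels call a mouse. The p-values of gene lists come from random draws of genes, not of mice, so they do not carry the uncertainty of 8 animals. Those of limma's test set a transcript's variance over the arrays against that of like transcripts, and those of score pairs permute the arrays.

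The arrays showed the profile of liver. Albumin (Alb), the main secreted protein of hepatocytes, had a signal of 31094 ± 749 (SD, n = 8), the urea cycle enzyme Cps1 24391 ± 759, the fetuin gene Ahsg 24406 ± 1224 and the retinol carrier Rbp4 19094 ± 560.4. α-Fetoprotein (Afp), a fetal liver and tumour marker, lay below the level filter at 103 ± 25.2. Among genes of the growth hormone and fasting axes, Igf1 was at 8518 ± 1464 with a 1.57-fold range over the 8 arrays, and Pck1, the first committed enzyme of gluconeogenesis, was at 5832 ± 940.2 with a 1.68-fold range. The chaperone Hspa5 was at 3990.2 ± 831, fatty acid synthase (Fasn) at 3065 ± 1169 and the desaturase Scd1 at 16270.1 ± 4068. Igfbp1, a binding protein of insulin-like growth factors induced by fasting, was at 919 ± 974, a mean carried by 3297 on replicate 6 against 363 to 773 on the others.

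On 7 of the 8 arrays the 3′ and 5′ control sets of Gapdh were about equally bright, and on replicate 5 they were not. The Gapdh 3′ set there read 13949, the middle set 3872 and the 5′ set 684, a log2 3′ over 5′ ratio of 4.35, against −0.24 to 0.33 elsewhere. For pyruvate carboxylase the ratio was 4.33 on replicate 5 and 4.30 on replicate 6, against 1.42 to 2.76 on the other 6, and for β-actin 1.34 on replicate 5 and 0.84 on replicate 6, against 0.53 to 0.76. The transferrin receptor sets were dim, with 5′ signals of 12.8 to 54.8, and their ratio was highest on replicate 1 (3.40) and 1.86 on replicate 5. The mean spike-in signal relative to all arrays ran from −0.38 on replicate 6 to 0.26 on replicate 3 on the log2 scale. Pairwise correlations over the kept probe sets had a median of 0.962 and ran from 0.870 to 0.979, and no 2 arrays held identical values. Replicate 5 had a median correlation of 0.881 with the others and replicate 6 of 0.943; without both, the 15 remaining pairs lay between 0.961 and 0.979. Replicate 5 held the lowest value of 28.3% and the highest value of 34.1% of the 4810 genes, and replicate 6 held 16.6% and 18.8%, where equal shares would be 12.5%.

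**Figure D1:**
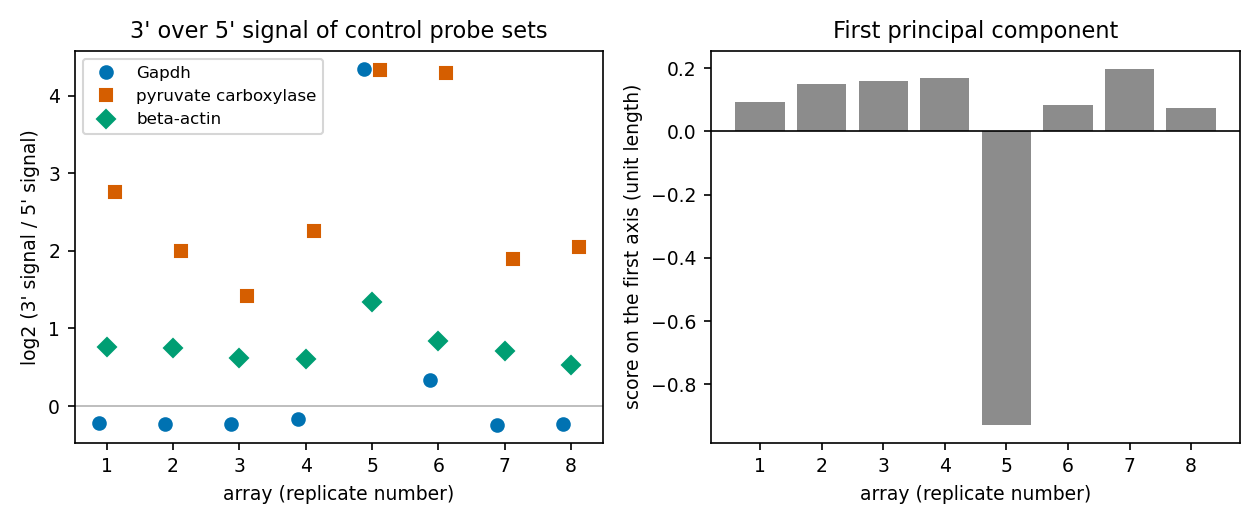
Left, log2 ratio of 3′ to 5′ signal of the control probe sets for Gapdh, pyruvate carboxylase and β-actin on each of the 8 arrays, 1 point per array. Right, each array's score on the first principal component, as bars; replicate 5 has a Gapdh ratio of 4.35 and the only negative score.

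Single transcripts were then compared with transcripts of like level, to find those that differed most between animals. The most variable named genes included Idi1 of sterol synthesis, the complement gene C1qa and Cyp7a1, the rate-limiting enzyme of bile acid synthesis. Idi1 ran from 335 on replicate 6 to 5114 on replicate 4 (15.3-fold). C1qa was 80.0 on replicate 5 and 768 to 1557 on the others, and Cyp7a1 was 201 on replicate 5, 1078 on replicate 6 and 1839.9 to 2349.6 elsewhere. Reg1, a gene of the exocrine pancreas, was 1968 on replicate 2 and 30.2 to 200.1 on the others, and the cytochrome Cyp2c39 was 10371 on replicate 3 and 1279 to 2132 on the others. None passed the test: limma called 0 of 6211 probe sets at an adjusted p of 0.05, with a lowest adjusted p of 0.842, and 0 adjusted over the listed genes alone. At an unadjusted p of 0.05 there were 352 probe sets, where the fitted distribution gives 311. Its prior was fitted to these same variances, so a count near 311 is largely built in. The test asks which transcripts exceed the common spread, and its counts do not show whether the animals differed. The median SD was 0.28 on the log2 scale, the median coefficient of variation 19.5%, and 2398 probe sets (38.6%) differed by more than 2-fold between their lowest and highest array. Without replicates 5 and 6 the median coefficient of variation was 13.2%. In simulated data of this size the test found 8% of probe sets whose own simulated SD was raised 4 times, and 90% of those raised 16 times. That SD was drawn around 1 common value and not set by level. These shares are therefore not the power for a multiple of the SD at a given level.

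Gene lists fixed beforehand were tested next, for whether a pathway or cell type differed more between animals than transcripts of like level (variability) and whether its genes rose and fell together (coherence). Of 29 lists, 6 passed for variability and 12 for coherence, and 3 passed for both: cholesterol synthesis, fatty acid synthesis and class II antigen presentation. Leaving out replicate 6 left 1 list past the variability threshold, leaving out replicate 5 gave 10, and the coherence count was 6 without replicate 6 and 7 without replicate 7.

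**Figure D2:**
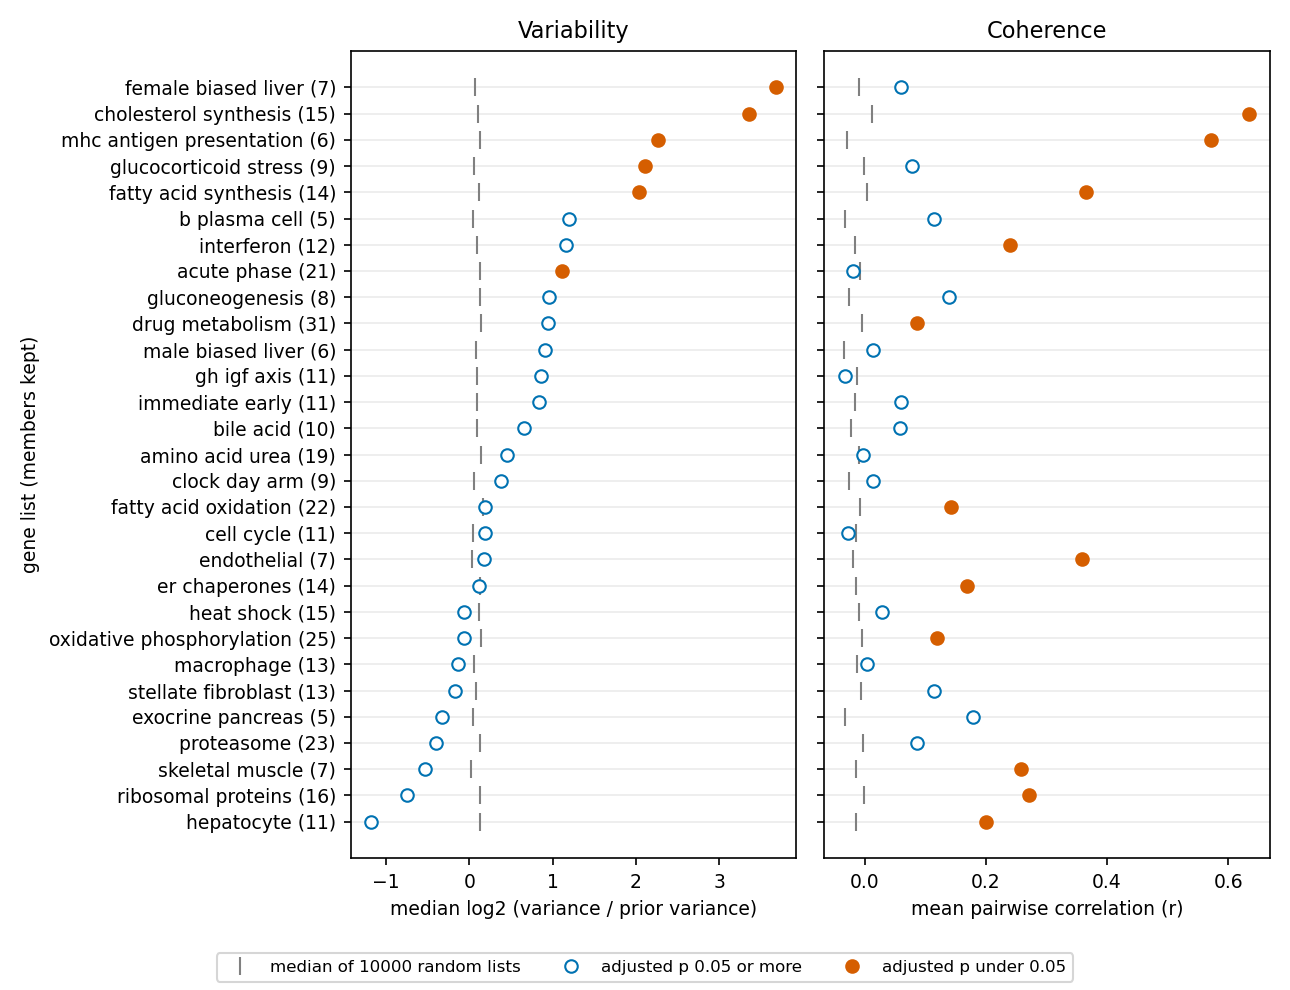
Median log2 variance ratio (left) and mean pairwise correlation across the 8 arrays (right) of the 29 gene lists, 1 circle per list with its number of kept genes in brackets; filled circles have an adjusted p under 0.05 and vertical ticks mark the median of 10000 random lists. Cholesterol synthesis lies at 3.35 and 0.635.

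Cholesterol synthesis genes were low together on replicate 6 and high together on replicate 4. The list (15 kept genes) had a median log2 variance ratio of 3.35 (adjusted p = 0.00193) and a mean pairwise correlation of 0.635 (adjusted p = 0.00290), with 13 of 15 genes more variable than their level. By limma's test 10 of the 15 passed unadjusted and 9 passed adjusted over the list alone. The lowest value of 10 genes was on replicate 6 and the highest of 9 was on replicate 4. Idi1, which isomerises the isoprene unit, was 3059.7 ± 1852, the demethylation enzyme Msmo1 1893 ± 1169.8 and the sterol dehydrogenase Nsdhl 1475 ± 849.7. The isoprenoid synthase Fdps was 5095 ± 2659.8 (1534 on replicate 6 and 9643 on replicate 4), Lss 713 ± 292 and Dhcr7 811 ± 310.4. The list score was lowest on replicate 6 at −1.22, then −0.60 on replicate 7, and highest on replicate 4 at 0.74. On replicate 5, where the Gapdh 5′ signal was low, Nsdhl was 376 while Msmo1 was 3886, its highest value. Both calls held under all 18 alternatives, though with the spike-in signal as covariate the ratio was 2.21 (adjusted p = 0.00290). Replicate 6, where the list was lowest, had the lowest spike-in signal (−0.38) and a pyruvate carboxylase ratio of 4.30.

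**Figure D3:**
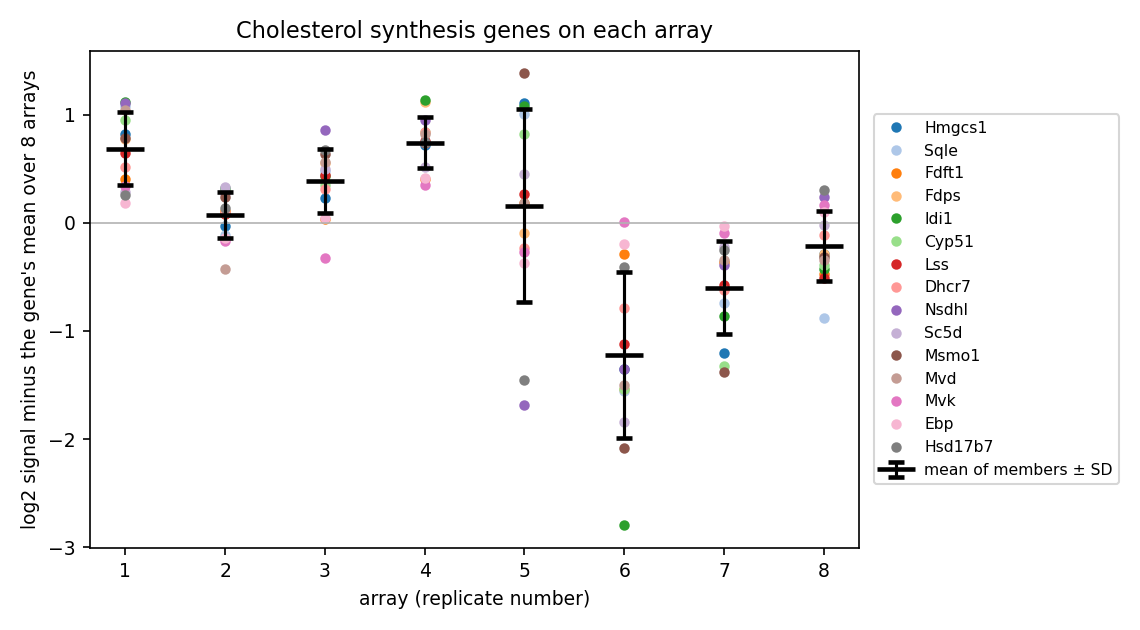
Log2 signal of the 15 cholesterol synthesis genes on each of the 8 arrays, minus each gene's own mean, 1 point per gene; the horizontal mark is the mean over the 15 genes and the bar its SD across genes. The mean is 0.74 on replicate 4 and −1.22 on replicate 6.

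Fatty acid synthesis genes (14 kept) were lowest on replicate 6 for 11 of 14. The median log2 variance ratio was 2.04 (adjusted p = 0.00193), the mean correlation 0.366 (adjusted p = 0.0232), 12 of 14 exceeded their level's variance, and by limma's test 3 passed unadjusted and 0 adjusted over the list alone. The elongase Elovl6 ranged from 540.2 on replicate 6 to 3278 on replicate 5. Scd1 was 7632 on replicate 6 and 14655 to 21577 on the others, Fasn 1550.4 and 2176 to 5258, and the lipogenic regulator Thrsp 4266 and 5393 to 9809. Elovl5 was low on both arrays with raised 3′ over 5′ ratios, 6917 on replicate 5 and 5699 on replicate 6, and 12092 to 13782 on the others. Without replicate 6 the ratio was 1.43 (adjusted p = 0.0507) and the mean correlation 0.113 (adjusted p = 0.238). With the spike-in signal removed the mean correlation was 0.301 and the coherence p 0.0551.

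Liver genes known to be higher in females than in males (7 kept) differed between animals beyond their level, with a median log2 variance ratio of 3.68 (adjusted p = 0.00193). All 7 exceeded their level's variance and 4 (Cyp17a1, Cyp2b13, Hao2 and the transcription factor Cux2) passed adjusted over the list alone, while the list did not pass for coherence (mean correlation 0.0606, adjusted p = 0.389). The cytochrome Cyp2b13 was 2654 ± 1208 and the peroxisomal oxidase Hao2 1756 ± 727, both lowest on replicate 6 (512 and 319). The steroid hydroxylase Cyp17a1 was 1118 ± 682, from 306 on replicate 1 to 2143 on replicate 6. Cyp2b13 and Cyp3a16 are members of the drug metabolism list as well. Male-biased genes (6 kept) did not pass either test (ratio 0.91, adjusted p = 0.355; correlation 0.0134, adjusted p = 0.426). In that list Serpina1e was 27624 ± 688, the urinary protein Mup3 22180.4 ± 2873, Cyp7b1 513 ± 187 and Egfr 440.4 ± 139. Without replicate 6 the ratio of the female-biased list was 1.503 (adjusted p = 0.0844).

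Glucocorticoid-responsive and metallothionein genes (9 kept) also varied (median log2 variance ratio 2.11, adjusted p = 0.0104), and 5 of 9 were highest on replicate 6. The metal-binding proteins Mt1 and Mt2 were 15672 and 13888 on replicate 6, against 3613 to 6014 and 1998 to 5461 on the others. The clock gene Per1 ranged from 157 on replicate 5 to 908 on replicate 6. The list did not pass for coherence (mean correlation 0.0781, adjusted p = 0.353), and the ratio was 1.45 without replicate 6 (adjusted p = 0.0844) and 3.23 without replicate 5 (adjusted p = 0.0015). Gluconeogenic and fasting genes (8 kept) did not pass (ratio 0.95, adjusted p = 0.310; correlation 0.140, adjusted p = 0.194), though 5 of 8 had their highest value on replicate 6. There glucose-6-phosphatase (G6pc) read 7281 against 2182 to 4911 elsewhere and tyrosine aminotransferase (Tat) 25038 against 12179 to 18470.5, while Fbp1 was 18484 ± 2001.

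**Figure D4:**
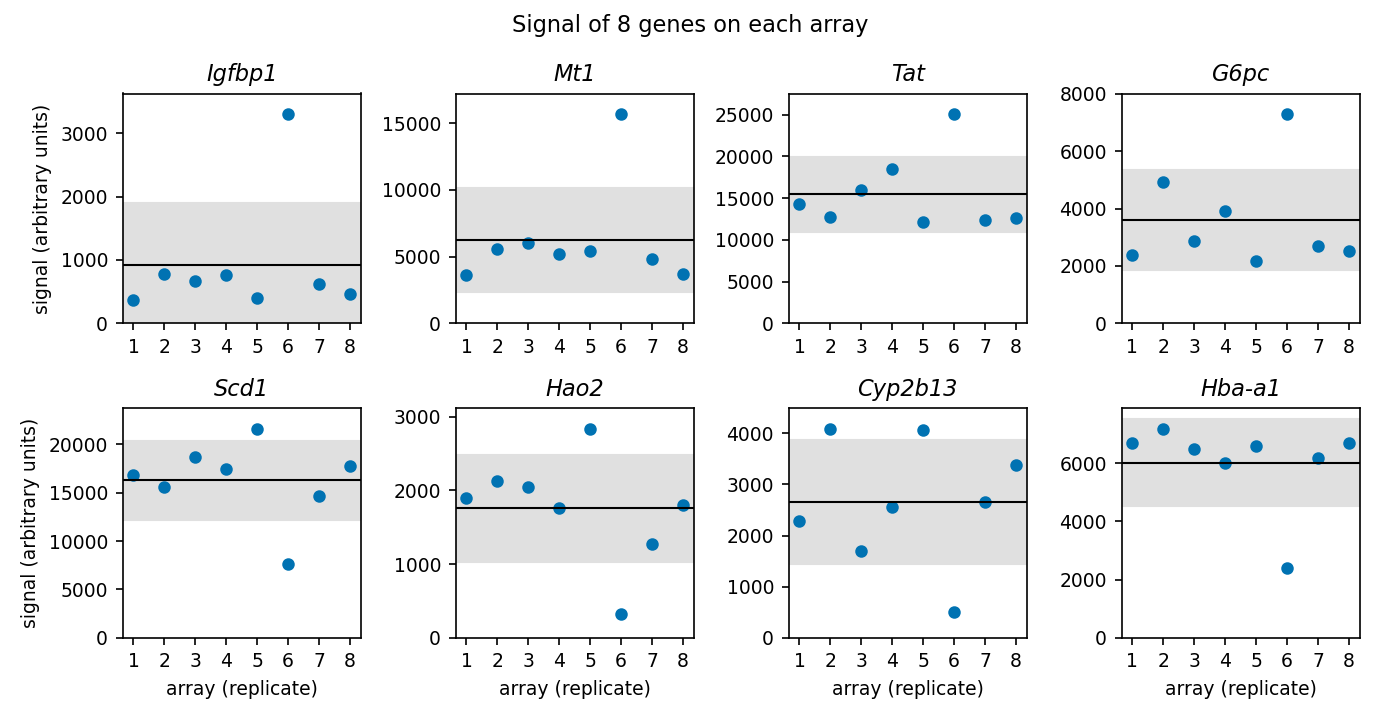
Signal of 8 genes on each of the 8 arrays, 1 point per array on a linear axis; the line is the mean and the grey band 1 SD either side, drawn from 0 where it would fall below. On replicate 6 Igfbp1 is 3297, Mt1 15672, Scd1 7632 and Hao2 319.

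Class II antigen presentation genes (6 kept), markers of antigen-presenting cells, varied and moved together (ratio 2.26, adjusted p = 0.0104; correlation 0.571, adjusted p = 0.0304). H2-Aa was 748 ± 393, H2-Ab1 433 ± 186 and the invariant chain Cd74 2529 ± 869.8, and for all 3 the highest array was replicate 4 and the lowest replicate 6. Scores of the marker lists of other cell types went both ways on replicate 6. Relative to the median of the arrays other than 5 and 6 they were −0.58 for endothelial, −0.52 for B and plasma cell, −0.29 for stellate cell, −0.16 for macrophage, −0.03 for exocrine pancreas and 0.14 for skeletal muscle genes on the log2 scale, beside −0.97 for antigen presentation. Scores relative to the mean of all arrays were highest there for the 3 neutrophil markers kept (0.51) and the 2 adipose ones, Pnpla2 and Lep (0.95). They were positive for the 2 T and NK cell markers (0.20). For the 3 erythroid markers kept the score was lowest there (−0.54). So few genes of a list do not show how much of a cell type or tissue was present. Interferon-induced genes (12 kept) moved together (correlation 0.240, adjusted p = 0.0304) without passing for variability (ratio 1.17, adjusted p = 0.0547). The GTPases Gbp3, Irgm1 and Igtp were 533 ± 267, 339 ± 140.1 and 590.3 ± 244, Ifi47 was 249 ± 97.2 and Ifi204 197 ± 70.7, and 5 of the 12 genes were lowest on replicate 6 and 5 on replicate 7. For antigen presentation the ratio was 1.96 (adjusted p = 0.0507) and the correlation 0.473 (adjusted p = 0.0615) without replicate 6, and the coherence p was 0.0643 without replicate 3 (correlation 0.337) and 0.0569 without shared-sequence probe sets, where the correlation stayed at 0.571. For interferon genes the coherence p was 0.303 without replicate 7 (correlation 0.0580), 0.0641 with the deposited scaling (correlation 0.211) and 0.0569 without shared-sequence probe sets (correlation 0.204). Their variability passed under 10 of 17 alternatives, with adjusted p-values of 0.0271, 0.0348, 0.0454, 0.00257 and 0.0380 without replicates 2, 3, 4, 5 and 8 and 0.00450 without both 5 and 6.

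Acute phase genes (21 kept) lay at the threshold for variability (ratio 1.12, adjusted p = 0.0493) and did not pass for coherence (correlation −0.0183, adjusted p = 0.665). The serum amyloid genes Saa4 and Saa3 were 890.1 ± 559 and 463 ± 460.5, the latter at 1569 on replicate 2 and 196 to 483 on the others, and Orm2 was 3141 ± 1335. The call held under 15 of 18 alternatives, with a ratio of 1.71 without replicate 5 (adjusted p = 0.0015) and an adjusted p of 0.0048 without both 5 and 6. It was lost without replicate 6 (ratio 1.15, adjusted p = 0.0507), with no level filter (3.97, 0.113) and with the stricter one (1.31, 0.0666). Without replicate 6 and with the stricter filter the ratio was no lower than with all arrays and the planned filter. With no filter the ratios lie on another scale and are not comparable: that of hepatocyte markers was 1.67 there, against −1.18 with the planned filter.

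Ribosomal protein genes (16 kept) moved together, with a mean correlation of 0.272 (adjusted p = 0.0174), and did not pass for variability (ratio −0.75, adjusted p = 0.180). Their highest value was on replicate 6 for 11 of 16, as for Rplp0 (12908 against 8175 to 10909.8), Rpl19 (9385 against 6855 to 9327), Rpl13a (452 against 286 to 361) and Rpl8 (7953 against 4457 to 7249). Rps19 was 1939 ± 481 and Rpl32 327 ± 76.3. Without replicate 6 the coherence was 0.0260 (adjusted p = 0.370), and without replicates 5 and 6 its p was 0.142, with a ratio of −1.30 that passed as low (adjusted p = 0.0150).

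Fatty acid oxidation genes (22 kept) moved together weakly (correlation 0.142, adjusted p = 0.0304) and did not pass for variability (ratio 0.19, adjusted p = 0.965). The dehydrogenase Acadm was 4476 ± 1024, Cyp4a10 5370.1 ± 716 and Hadhb 5349 ± 510.0, each lowest on replicate 7. The peroxisome gene Pex11a ranged from 157 on replicate 5 to 1613 on replicate 2, Acot1 was 1196 on replicate 6 and 328 to 554 on the others, and Vnn1 was 333 ± 133. The coherence p was 0.124 without replicate 2, 0.0738 without replicate 7 and 0.0569 without shared-sequence probe sets, and the correlation was 0.222 without replicate 6 (adjusted p = 0.0266). Respiratory chain genes (25 kept) had a mean correlation of 0.120 (adjusted p = 0.0304) and a ratio of −0.07 (adjusted p = 0.743), and 14 of 25 were highest on replicate 5, the array with low Gapdh 5′ signal. Cox7a2 was 8799 there and 5271 to 5881 elsewhere, Atp5k 1096 and 382 to 614, Cycs 1027 and 432 to 638, and Uqcrh 5989 and 4026 to 5298, whereas Ndufv1 was lowest there (4352 against 6733 to 10444). Its coherence p was 0.0630 without replicate 8, 0.0568 with the mean over probe sets and 0.501 without shared-sequence probe sets.

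Drug-metabolising enzymes (31 kept) had a mean correlation of 0.0862 (adjusted p = 0.0304) and a ratio of 0.95 (adjusted p = 0.0587), and 12 of 31 were lowest on replicate 6. Gstm3, Cyp3a16 and Cyp3a25 had the highest correlations with the rest, at 8586 ± 989.8, 349 ± 71.3 and 5525 ± 604, and Cyp2f2 ranged from 1572 on replicate 5 to 6462 on replicate 7. The coherence p was 0.241 without replicate 3, 0.0615 without replicate 6 and 0.0804 without replicate 7, and between 0.0547 and 0.258 under 4 other alternatives. Variability passed without replicate 2 (adjusted p = 0.0287), without replicate 5 (0.0255), with the first component removed (0.0239) and with the spike-in covariate (0.0319), and without replicate 6 the ratio was 0.18 (adjusted p = 0.964).

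Endoplasmic reticulum chaperones (14 kept) were lowest on replicate 5 for 10 of 14, beside its low Gapdh 5′ signal. Hspa5 was 2138 there and 3846 to 4823 elsewhere, and the disulfide isomerases Pdia4, Pdia6 and P4hb were 283, 459 and 1115, against 829 to 1524, 1275 to 1856 and 2049 to 3756. The mean correlation was 0.169 (adjusted p = 0.0446) and the ratio 0.11 (adjusted p = 0.965). Without replicate 5 the mean correlation was 0.0144 (adjusted p = 0.344). The p was 0.0525 without replicate 3 (correlation 0.172), 0.0585 without 4 (0.159), 0.0652 without 6 (0.191) and 0.0738 without 7 (0.154). The call held under 6 of 18 alternatives, and without replicates 5 and 6 the mean correlation was −0.0253. Hepatocyte markers (11 kept) had a mean correlation of 0.201 (adjusted p = 0.0304) and a ratio of −1.18 (adjusted p = 0.0786), with 5 of 11 lowest on replicate 5. Serpinc1 and Vtn were 9327 and 8235 there against 13888 to 15374 and 11886 to 14281, Apob ranged from 1267 to 5208, and F2 was 9981 ± 992. The hepatocyte coherence p was 0.159 without replicate 5, 0.0791 without replicate 8 and 0.0719 with the deposited scaling (correlation 0.210, no lower than 0.201), and between 0.0577 and 0.199 under 3 other alternatives, while a ratio below that of the random lists passed without replicate 2 (−1.47, adjusted p = 0.0336), without replicate 7 (−1.92, 0.0116), and at adjusted p-values of 0.0197 to 0.0442 under 3 others.

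Markers of other cell types were measured beside them. Endothelial markers (7 kept) moved together (correlation 0.359, adjusted p = 0.0304; ratio 0.18, adjusted p = 0.869), with 5 of 7 lowest on replicate 6: Kdr was 126 there and 210.4 to 411 elsewhere, Cdh5 239 and 294 to 473, Ramp2 282 and 304 to 493, and Flt4 508 and 551 to 749. Tie1 was 335 ± 76.4. The p was 0.0635 without replicate 4, and without replicate 6 the correlation was 0.132 (adjusted p = 0.303). Skeletal muscle markers (7 kept), a check for carried-over tissue, correlated at 0.258 (adjusted p = 0.0483; ratio −0.54, adjusted p = 0.475). The parvalbumin gene Pvalb was 1225 ± 162, the calcium pump Atp2a1 217 ± 142 with its highest value of 439 on replicate 7, Myh4 162 ± 62.0, Mylpf 189 ± 50.9 and Tnnc2 155 ± 39.5. Without replicate 7 the mean correlation was −0.00534 (adjusted p = 0.490), the p without replicates 1, 3, 4, 5 or 8 was 0.145, 0.0916, 0.0589, 0.101 and 0.105, with the higher floor 0.165, with the mean over probe sets 0.0568, and a second draw of the random lists gave 0.0520. The correlation was 0.269 without replicate 4 and stayed at 0.258 in the last 2 of these.

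Besides gluconeogenesis and the male-biased genes, 12 other lists passed neither test. Growth hormone and IGF axis genes (11 kept) had a ratio of 0.86 (adjusted p = 0.310) and a correlation of −0.0322 (adjusted p = 0.657). The binding proteins Igfbp2 and Igfbp4 were 10576 ± 3543 and 7388 ± 2237, both lowest on replicate 5 (3720.5 and 2194). Bile acid genes (10 kept) had a ratio of 0.66 (adjusted p = 0.456) and a correlation of 0.0589 (adjusted p = 0.274), with the transporter Slc10a1 at 11799 ± 1189.6, Slc27a5 at 7448 ± 779.5 and Abcc2 at 621 ± 219. Amino acid and urea genes (19 kept) had a ratio of 0.46 (adjusted p = 0.554) and a correlation of −0.00309 (adjusted p = 0.464), with Tdo2 at 21420.4 ± 2168, Bhmt at 13242 ± 3319 and Asl at 339 ± 168. Clock genes with the phase of Dbp (9 kept) had a ratio of 0.38 (adjusted p = 0.743) and a correlation of 0.0138 (adjusted p = 0.401), with Tef at 2808 ± 428, Usp2 at 1955 ± 353 and Per3 at 1009.8 ± 305. Heat shock chaperones (15 kept) had a ratio of −0.06 (adjusted p = 0.839) and a correlation of 0.0285 (adjusted p = 0.333), with Hspd1 at 11118 ± 2331, Hspe1 at 6928 ± 763 and Stip1 at 378 ± 109. Immediate early genes (11 kept) had a ratio of 0.84 (adjusted p = 0.299) and a correlation of 0.0603 (adjusted p = 0.242), with Jund at 3648 ± 693, Zfp36 at 924 ± 223, Gadd45a at 273 ± 149 and Btg2 at 423 ± 119.8. Cell cycle genes (11 kept) had a ratio of 0.19 (adjusted p = 0.839) and a correlation of −0.0276 (adjusted p = 0.652), with Tk1 at 1369 ± 335 and Ccnd1 at 935 ± 257. Proteasome subunits (23 kept) had a ratio of −0.39 (adjusted p = 0.310) and a correlation of 0.0870 (adjusted p = 0.0642), with Psma3 at 5413 ± 877, Psmb4 at 4063 ± 357, Psmd13 at 848 ± 224 and Psma6 at 3277 ± 1166. Proteasome coherence passed under 5 alternatives: without replicate 5 (correlation 0.193, adjusted p = 0.00420), without replicate 2 (0.102, 0.0467), without both 5 and 6 (0.234, 0.0010), with the first component removed (0.160, 0.00994) and with the deposited scaling (0.126, 0.0461). Without replicate 5 bile acid variability passed as well (ratio 1.37, adjusted p = 0.0400), and with both 5 and 6 left out so did bile acid coherence (0.231, 0.0297) and immediate early variability (1.57, 0.0050). With the higher floor the growth hormone and IGF axis passed for variability (1.96, adjusted p = 0.00840).

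Among cell type markers, Kupffer cell and macrophage genes (13 kept) had a ratio of −0.13 (adjusted p = 0.826) and a correlation of 0.00381 (adjusted p = 0.430), with the Kupffer cell lectin Clec4f at 1432 ± 194, C1qc at 1339.5 ± 181 and Lyz2 at 399 ± 143. Stellate cell and fibroblast genes (13 kept) had a ratio of −0.17 (adjusted p = 0.743) and a correlation of 0.114 (adjusted p = 0.108), and 6 of 13 were lowest on replicate 6, Dcn at 2952 against 3840.0 to 4679.9, Col3a1 at 66.3 against 142 to 276 and Sparc at 282 against 367 to 804. Col1a2 was 1669 ± 185. B and plasma cell genes (5 kept) had a ratio of 1.19 (adjusted p = 0.246) and a correlation of 0.115 (adjusted p = 0.307), with Ighm at 368 ± 94.2, Igha at 358 ± 198 and Igll1 at 178 ± 59.9. Exocrine pancreas genes (5 kept) had a ratio of −0.32 (adjusted p = 0.743) and a correlation of 0.178 (adjusted p = 0.194), with the elastase Cela1 at 858 ± 449.8 and Ctrb1 at 673 ± 94.1. The B and plasma cell list passed for variability without replicate 5 (ratio 1.89, adjusted p = 0.0402), macrophage genes for coherence without replicates 5 and 6 (0.150, adjusted p = 0.0430) and stellate cell genes for coherence with no level filter (0.172, adjusted p = 0.0257). Too few genes of 7 lists were kept for a test: 0 of 10 cholangiocyte markers, 2 of 21 T and NK cell markers (Zap70 at 1323 ± 299, Cd4 at 222 ± 64.9), 3 of 12 neutrophil markers (Csf3r at 855 ± 146, Elane at 212 ± 65.9, Camp at 195 ± 76.3), 3 of 11 erythroid markers (Hba-a1 at 6022 ± 1508, Alas2 at 505 ± 125), 4 of 10 fetal and tumour genes (Dlk1 at 306 ± 61.4, Golm1 at 281 ± 64.1, Prom1 at 283 ± 108, Cd24a at 227 ± 63.6), 2 of 9 adipose markers (Pnpla2 at 2506 ± 1040.0, Lep at 1164 ± 452) and 2 of 5 clock genes of the opposite phase (Cry1 at 416 ± 129, Nfil3 at 172 ± 44.7). By limma's test adjusted over the list alone, 1 gene passed in each of the bile acid (Cyp7a1), macrophage (C1qa) and exocrine pancreas (Reg1) lists, beside those of cholesterol synthesis and the female-biased list, and 0 in the other 31 of the 36 lists, where unadjusted counts ran from 0 to 5. This adjustment does not cover the number of lists. The log2 variance ratio was 4.63 for Cyp7a1, 4.98 for C1qa and 4.33 for Reg1 with all arrays. Without replicates 5 and 6 it was −0.35, 0.89 and 5.17. Hba-a1, the haemoglobin alpha chain of red cells, was 2395 on replicate 6 and 5989 to 7174 on the others.

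Whether pathways moved with each other was tested for 14 pairs of list scores, and 0 passed after adjustment. The fatty acid and cholesterol synthesis scores had r = 0.76 (exact permutation p = 0.0306, adjusted 0.209; Spearman's rho = 0.71, exact p = 0.0576). The fatty acid synthesis and gluconeogenesis scores had r = −0.82 (exact permutation p = 0.0308, adjusted 0.209) and rho = −0.62 (exact p = 0.115), and the glucocorticoid and gluconeogenesis scores, whose lists share Tat, had r = 0.83 (exact permutation p = 0.0448, adjusted 0.209) and rho = 0.48 (exact p = 0.243). Adjusted values for rho were at least 0.551 in all 14 pairs. Without the 2 arrays farthest from the median of the first score, r was 0.48, 0.15 and 0.42, and without replicate 6 alone 0.37, −0.29 and 0.20, so these 3 relations rest on few arrays. The other 11 pairs had r between −0.40 and 0.35 with exact permutation p-values of 0.362 or more, and rho between −0.55 and 0.52 with exact p-values of 0.171 or more. Of these, cholesterol synthesis with bile acid genes went from r = −0.21 to −0.59 without replicate 6 and −0.84 without both 5 and 6 (exact permutation p = 0.0528, adjusted 0.739), and the 2 clock lists from −0.38 to −0.68 without replicate 6.

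The leading axis of variation asked which genes lie along the main difference between arrays, which holds both animal and technical differences. It carried 46.2% of the variance, against at most 15.6% in shuffled data (permutation p = 0.001, the smallest they can give). Shuffling each probe set on its own removes every array-wide difference, so 1 array lying apart is enough for that p. Replicate 5 held 86.2% of the squared scores, and its Gapdh log2 3′ over 5′ ratio was 4.35, so the axis cannot be read as a difference between animals alone. No list lay along it: the endoplasmic reticulum chaperones (mean correlation with the axis 0.43) and the respiratory chain (−0.32) came closest, each with an adjusted p of 0.194. Without replicate 5 the first axis carried 36.5%, replicate 6 held 76.2% of its squared scores, and 3 lists passed. Cholesterol synthesis (mean correlation with the axis 0.68) and fatty acid synthesis (0.59) lay away from replicate 6 and the ribosomal proteins (−0.60) toward it, each with an adjusted p of 0.0020, the smallest the random lists allowed. Without replicates 5 and 6 the share was 31.5% and 7 lists passed.

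Probe sets whose names mark possibly shared sequence were those of Alas2, Atp2a1, Col1a2, Cry1, Ctrb1, Cyp3a16, Cyp4a10, Cyp7b1, Egfr, Gstm3, Ifi204, Igf1, Igfbp1, Igfbp4, Ighm, Mup3, Myh4, Nfil3, Nsdhl, P4hb, Pdia6, Psma3, Psmb4, Pvalb, Rpl32, Serpina1e, Slc10a1, Tdo2, Tnnc2, Zap70 and Zfp36, so related transcripts can add to their signals. Kept probe sets of the same gene went in opposite directions across arrays for Hspd1 (r = −0.74), Zap70 (r = −0.64), Pdia6 (r = −0.63), Igf1 (r = −0.55), Tdo2 (r = −0.52), P4hb (r = −0.30), Tie1 (r = −0.10), and values above are those of the brightest set.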

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

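Of the tests in this part, those of an explanation were chosen after the result was seen, except the tests that remove the spike-in signal, chosen before their result was known; the search for arrays far from the others was planned.

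Each value below is the gap between the highest or lowest array and the nearest other, as a share of the whole range, where it exceeded Dixon's 95% critical value for 8 arrays. Chance gives about 1 in 20 such values in groups not chosen by their spread, whereas most genes here were named for a high variance, which a single far array raises, so no excess over chance is read from their count. The value was exceeded by 39 of 137 genes, 9 of 29 list scores, 2 of 3 control ratios, the first principal component, the median correlation and 0 of 1 spike-in measures. On replicate 5 the first component stood apart (0.888), as did the median correlation with the other arrays (0.667, low) and the 3′ over 5′ ratios of Gapdh (0.875) and β-actin (0.612). The scores of the endoplasmic reticulum chaperones (0.781) and the growth hormone and IGF axis (0.615) were low there. Genes low on replicate 5 were Igfbp4 (0.797), Serpinc1 (0.797), C1qa (0.762), Pdia6 (0.731), Hspa5 (0.722), Psmd13 (0.702), Cyp7a1 (0.683), Stip1 (0.680), Vtn (0.667), Pdia4 (0.638), Lep (0.612), C1qc (0.608), Igfbp2 (0.596), Per3 (0.587), Pex11a (0.569) and Tk1 (0.542), and genes high there were Cox7a2 (0.786), Psma6 (0.732), Atp5k (0.551) and Cycs (0.5499). On replicate 6 the scores of gluconeogenesis (0.620), ribosomal proteins (0.585), glucocorticoid-responsive genes (0.534) and amino acid and urea genes (0.531) were high, and those of endothelial (0.547) and stellate cell genes (0.531) low. Genes low on replicate 6 were Hba-a1 (0.835), Hao2 (0.633), Scd1 (0.628), Cyp2b13 (0.578), Dcn (0.571), Ccnd1 (0.560) and Col3a1 (0.535), and genes high there were Igfbp1 (0.658), Mt1 (0.653) and Acot1 (0.596). Replicate 2 was high for Igha (0.605), Saa3 (0.567) and Reg1 (0.547) and low for Cps1 (0.588). Replicate 3 was high for Cyp2c39 (0.756) and low for Zap70 (0.539), replicate 4 was low for Btg2 (0.55), replicate 7 was high for Tnnc2 (0.579) and for the cell cycle score (0.794), and replicate 8 was low for Alb (0.536). For Alb and Cps1, among the brightest transcripts, the gap is the spacing of the top values that quantile normalization gives every array, not a measured difference between animals.

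Replicate 5 lay apart from the 7 other arrays over the whole transcriptome. Its spike-in signal lay 0.0055 above the mean of all arrays on the log2 scale, within the −0.38 to 0.26 of the others. That signal was read on values already scaled to a like mean on each array, so it cannot decide on weak labelling or hybridisation. With the deposited scaling replicate 5 kept the largest score on a first component carrying 50.3% of the variance, which argues against the scaling. Of the 3 brighter control genes 3 had their highest 3′ over 5′ ratio on replicate 5, Gapdh by 4.49 on the log2 scale or 21.4 SD of the others (mean −0.14 ± 0.21, SD, n = 7), so loss of 5′ RNA sequence is a candidate explanation, found and tested on the same arrays. The dim transferrin receptor sets did not show it, with a ratio of 1.86 there and 3.40 on replicate 1. The labels name no factor that differs among the 8 mice, so no biological explanation was tested.

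Cholesterol synthesis genes moved together, with a mean pairwise correlation of 0.635 over 8 arrays. Without replicates 5 and 6 it was 0.778 (adjusted p = 0.0010, the smallest the random lists could give), against RNA quality of those arrays as the whole cause, and the lowest value with 1 array left out was 0.560 (highest adjusted p 0.0203), against a single array. With the spike-in signal removed it was 0.464 (adjusted p = 0.0348), against a trend along that signal as the whole cause. The list score and the spike-in signal were nevertheless both positive on replicates 1 to 5 and both negative on replicates 6 to 8. A large part of the shared movement along that technical signal therefore stays open. A shared regulation of the pathway that differed between animals remains a hypothesis, found and tested on the same data. Feeding state, time of day at death and genotype are not among the labels used here and stay open.

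Replicate 6 was the extreme array for 11 of 29 list scores (37.9%, where equal shares give 12.5%), and replicate 5 for 6. In 6 of those 11 lists (54.5%) replicate 5 deviated in the same direction, close to the even split of chance, so a 5′ loss shared with replicate 5 stays open. The pyruvate carboxylase ratio of replicate 6 was 4.30 and, of 124 genes whose 2 lowest arrays lay over 0.5 below the next on the log2 scale, 42 had replicates 5 and 6 as that pair. The same 2 arrays were also the highest pair in 11 of 35 genes with such a gap below the 2 highest. Replicates 5 and 6 each held the lowest value more often than an equal share (28.3% and 16.6% against 12.5%). The 42 genes thus do not by themselves show a shared cause. Unlike the pyruvate carboxylase ratio, the Gapdh ratio of replicate 6 was 0.33, against 4.35 on replicate 5. Across genes the deviations of the 2 arrays had a correlation of 0.0837. With the spike-in signal removed replicate 6 was extreme for 27.6% of the lists, but the bound set in advance against weak labelling or hybridisation, over 40%, lay above the uncorrected 37.9%, so this explanation and a difference of that animal cannot be told apart here, replicate 6 having the lowest spike-in signal (−0.38). No biological factor among the animals was tested.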

How the results depend on the processing

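The settings without replicates 5 and 6, with the spike-in signal as covariate and with a second draw of random lists were chosen after the data were seen; the others were planned. Across all results and settings, 64 values lost a call, 38 gained one, 6 moved by more than the spread and 1 reversed. The other 3795 kept their side of the threshold or stayed within the spread, though uncalled pair values among them could change direction. Of the 3795, 2512 were variance ratios of single genes and 262 were pair correlations. Neither kind passed under any setting, so their number says little about the list calls. Directions of lists were taken against the median of the random lists. No probe set passed limma's test under any of 19 alternatives, no pair of scores passed under 19, and the median correlation stayed between 0.947 and 0.971 under 14. The share of the first component was 46.2%, 31.6% with no filter, 53.3% with the filter at the 75th percentile, 31.5% without replicates 5 and 6, 53.4% with the spike-in covariate, and 36.5% to 56.9% with 1 array left out (lowest without replicate 5, highest without replicate 6). The lists along it numbered 0, 7 without replicates 5 and 6, and 0 to 3 with 1 array left out (3 without replicate 5). The lists variable beyond their level numbered 6, 3 with the 75th percentile filter, 11 with the first component removed, and 1 to 10 with 1 array left out (1 without replicate 6, 10 without replicate 5). The coherent lists numbered 12, 7 with the 75th percentile filter, 5 without shared-sequence probe sets, and 6 to 12 with 1 array left out (6 without replicate 6, 7 without replicate 7). The 75th percentile filter and the removal of shared-sequence probe sets left fewer genes to test. Without shared-sequence probe sets the mean correlation also fell for the respiratory chain (0.120 to 0.00156) and drug metabolism (0.0862 to 0.0434). For antigen presentation it stayed at 0.571. The causes of these and the other changes were not tested. Of 18 list calls, 2 held under every alternative, both of cholesterol synthesis, and 11 were lost without replicate 6, among them acute phase variability and endoplasmic reticulum chaperone coherence, whose values there (1.15 and 0.191) were no lower than with all arrays (1.12 and 0.169). The coherence of endoplasmic reticulum chaperones reversed without replicates 5 and 6, to −0.0253; the cause was not tested. Acute phase variability (0.0493), skeletal muscle coherence (0.0483) and endoplasmic reticulum chaperone coherence (0.0446) lay near the threshold, and the second draw ended that of skeletal muscle (0.052) and no other. Among values that passed no test, 67 of 1012 list values and 25 of 262 pair values changed direction. Some settings left fewer than 5 genes in a list, or none in the clock genes of the Bmal1 phase, and gave no value there. A probe set near the floor of 24.6 has little signal over background, and about 20% of values on each array lay at that floor. No paired analysis was possible because the samples form 1 group.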

Other observations

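The genes in this part, and the gaps used to find them, were chosen after their values were seen. In 6 genes the arrays fell into 2 sets of at least 2, more than 1.5 apart on the log2 scale. For the RIKEN transcript 0610005C13Rik, replicates 1, 4 and 5 read 575, 581 and 674, and the other 5 read 3689 to 5673. Notch2, a receptor of cell fate signalling, was 73.0 to 91.7 on replicates 1, 2, 3 and 5 and 264 to 302 on replicates 4, 6, 7 and 8. Hopx, a homeodomain protein, was 1201 on replicate 5 and 1179 on replicate 7, and 275 to 316 on the others. The remaining 3 were low on replicates 5 and 6, the arrays with raised 3′ over 5′ ratios of pyruvate carboxylase. The kinase Hipk2 was 25.4 and 15.4 there and 331 to 592 elsewhere. The stress kinase Mapk9 was 38.7 and 63.8 there and 229 to 345 elsewhere, and the bicarbonate transporter Slc4a4 59.9 and 37.0, and 199 to 351.

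Of 124 genes whose 2 lowest arrays lay over 0.5 on the log2 scale below the next, 42 had replicates 5 and 6 as that pair out of 28 possible pairs, 15 had replicates 6 and 7 and 10 had replicates 4 and 5. Of 35 genes with such a gap below the 2 highest arrays, 11 had replicates 5 and 6 as that pair. Across genes, which are not independent replicates, the deviations of replicates 5 and 6 had a correlation of 0.0837. The 3′ control set of β-actin ran from 838 on replicate 5 to 8534 on replicate 7 on the deposited scale. The 2 other probe sets named for Actb ran from 383 to 1114 and from 1103 to 2688.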
